A study of Mus musculus with 6 samples.

How the data were processed

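RNA-seq was carried out on whole mouse fetuses of the C57BL/6 strain at 9.0 days post coitum, 3 wild-type (WT) and 3 with overexpression of KLF12, a zinc-finger transcription factor. RNA was extracted with Trizol, per the labels' protocols. The labels do not say whether a sample is 1 fetus or a pool, so the p-values measure the spread between these samples, which may be partly technical.

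The authors deposited one table of FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments), rounded to 2 decimals, with 6 value columns. CASAVA, HISAT2 2.0.4, RSEM 1.2.8 and the mm9 build are named, per the submitters' processing notes, which were used here without role or order. The table held 17741 rows. Of these, 16874 matched an NCBI gene number in the GRCm38.p6 gene table, which gave the symbols, 777 carried names beginning with BGI_novel and 90 numbers had no symbol. No coordinates are given because that table is of a later assembly.

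The file holds no counts, so no count test was run. Low values were examined for the step that 1 fragment makes. With transcript lengths from GENCODE M21, FPKM times length in kilobases had a periodic step of 0.063 to 0.067 in the 6 libraries, with a coherence of 0.242 to 0.297, against at most 0.181 in 100 shuffles of the lengths. This corresponds to an estimate of 14900000 to 15900000 fragments per library. Whole fragments were not recovered for single genes.

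Values were analysed as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with an intensity trend in the variance, for the 12141 genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes are on this scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The level of Klf12 was also compared with a two-sided exact permutation test, which cannot give a p under 0.1 for 3 samples against 3.

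Before the data were examined, 35 gene lists were fixed, and 31 had the 5 tested members needed for limma's camera test with a preset inter-gene correlation of 0.01. Estimated correlations and the fry test served as alternatives. The genes named were also fixed by rule: Klf12, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 called members of each list or, failing these, the 2 with the smallest unadjusted p, and Tfap2a, Pax3, Vangl2, Grhl3 and Shh. Not all genes that this rule names are reported here.

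The fit and list test were tested on simulated data with the spread of the 12141 real genes. Of 100 genes changed by 1 on the log2 scale 68% were recovered, and of 100 changed by 2, 96%, with 11 unchanged genes called. A simulated list of 30 genes shifted by 0.5 was called, and 0 of the unchanged lists were. The simulated genes were independent, unlike real ones.

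The alternatives covered the pseudocount, the filter, the scaling, the variance model, a replicate block, each replicate left out and the list test. Removal of each library's transcript length trend, and a fit of the 4 libraries with Y-linked values above 0, were added after seeing the data.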

Results

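The study asked how a high level of KLF12 leads to neural tube defects, by comparing the transcriptomes of 9.0 dpc WT and KLF12-overexpressing fetuses (n = 3 each). FPKM summed to between 528236 and 635381 per library. The estimated depth was 14900000 to 15900000 fragments per library. Correlations of log2 values were 0.975 to 0.978 between WT libraries, 0.951 to 0.972 between KLF12 libraries and 0.955 to 0.969 between the groups. KLF12 library 3 correlated by 0.957 and 0.951 with KLF12 libraries 1 and 2, and by 0.955 to 0.959 with WT libraries. On the first principal component (31.5% of the variance) it lay at -2.13. KLF12 libraries 1 and 2 lay at 28.6 and 26.5 there, and WT libraries at -24.1 to -8.87. KLF12 library 3 stood apart on the second principal component, which held 28.6% of the variance. Y-linked genes differed within the KLF12 group: Ddx3y was listed at 0 in libraries 1 and 2 and at 6.62 FPKM in library 3, against 1.80, 4.45 and 2.63 in the WT libraries.

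Klf12 (NCBI gene 16597) was measured at 18.5 ± 4.75 FPKM in the overexpressing fetuses and 1.81 ± 0.426 in WT (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). All 3 libraries of the first group lay above all 3 of the second. In limma the log2 difference was 2.78 ± 0.22 (SE), adjusted p = 0.00113.

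Of 12141 genes, 89 were called by limma, 12 higher and 77 lower in the KLF12 group. S100a10, an S100 family protein that binds annexin A2, fell from 114 ± 4.71 to 11.0 ± 7.58 FPKM. Anxa6, an annexin that binds membrane phospholipid, fell from 47.0 ± 2.06 to 7.41 ± 1.51 FPKM. Gng2, a G protein gamma subunit, fell from 14.6 ± 1.34 to 1.02 ± 0.547 FPKM, and Tubb3, a neuronal beta-tubulin, from 16.6 ± 1.04 to 1.74 ± 1.45 FPKM (SD, n = 3). Among the higher genes, Adm, encoding the vasoactive peptide adrenomedullin, rose from 0.897 ± 0.216 to 7.68 ± 3.25 FPKM, and Pou3f1, a POU transcription factor, from 1.62 ± 0.715 to 6.53 ± 1.501 FPKM.

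The other large falls were in Tspo, Crip1, Sfn, Rad9a and Cd59b, with log2 changes of -2.54, -2.46, -2.26, -2.51 and -2.47, and in the unannotated row BGI_novel_G000106 at -3.13. Rad9a and Cd59b were listed at 0 in KLF12 libraries 2 and 3. The other large rises were in Trh, Ddit4, Zcwpw1 and Rps6kb2, with log2 changes of 1.94, 1.48, 1.44 and 2.23, and in the rows BGI_novel_G000001, BGI_novel_G000105 and BGI_novel_G000891. The row BGI_novel_G000105 was listed at 0 in each WT library, and Rps6kb2 at 0 in WT libraries 2 and 3. BGI_novel_G000106 was listed at 0 to 0.01 FPKM in the KLF12 libraries. The number of called genes depended on single libraries: it was 25, 22 and 17 without WT library 1, 2 or 3, 45 without KLF12 library 1, 64 without KLF12 library 2 and 326 without KLF12 library 3. It was 919 in the 4 libraries with Y-linked values, where the lone KLF12 library is assumed to vary like WT.

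**Figure D1:**
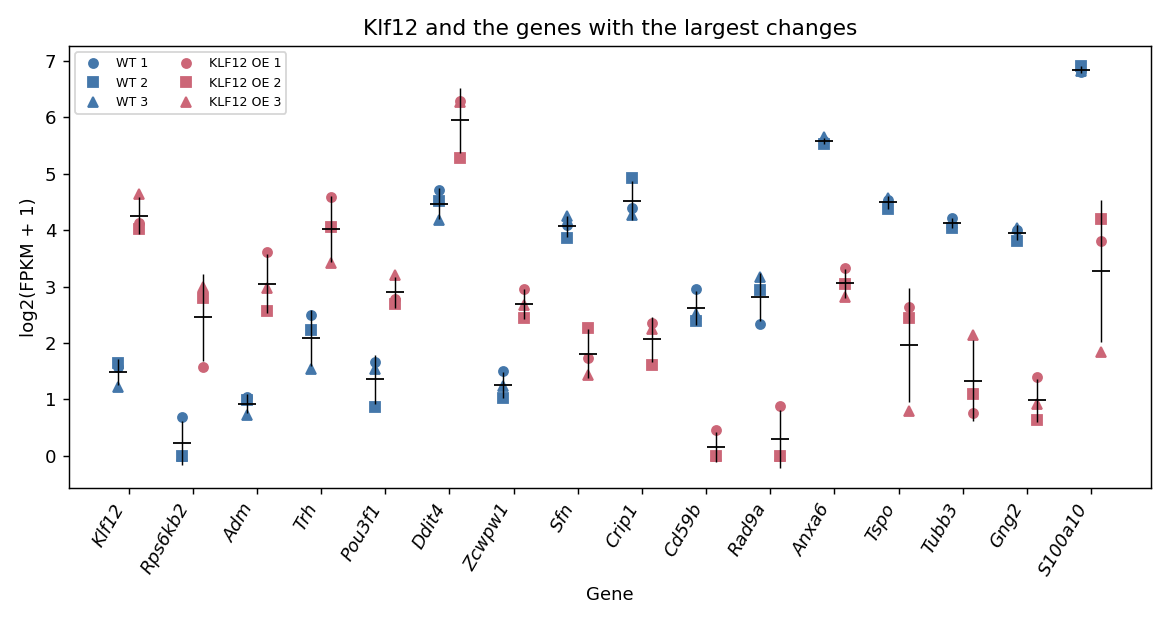
Values of Klf12 and the named genes with the largest changes, as log2(FPKM + 1) on the vertical axis, for each of the 6 libraries, with black bars for the mean and SD of each group (n = 3). The Klf12 values were 15.2 to 23.9 FPKM in the KLF12 libraries and 1.32 to 2.11 in WT.

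Neural tube closure genes were not called: 0 of 76 passed over all genes and 1 fell adjusted over the list alone. Spint2, a protease inhibitor, was at 65.1 ± 3.50 FPKM in WT and 41.2 ± 4.55 in the KLF12 group (limma adjusted p = 0.0652). Grhl3, a grainyhead transcription factor needed for spinal closure in mice, was at 5.64 ± 0.0985 and 2.79 ± 1.09 (adjusted p = 0.209). Tfap2a was at 8.43 ± 1.37 and 6.59 ± 2.07, Pax3 at 7.08 ± 1.13 and 6.13 ± 2.05, Vangl2 at 19.6 ± 1.78 and 24.3 ± 8.15, and Shh at 2.75 ± 1.77 and 8.50 ± 2.78 FPKM (SD, n = 3), none called by limma. The list's camera adjusted p was 0.736; without KLF12 library 3 it was 0.00183, with lower values, and in the 4 libraries with Y-linked values it was 9.02e-05, with higher values. Planar cell polarity genes, 0 of 32 called, had a camera adjusted p of 0.850, and 0.0297 without KLF12 library 2.

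Of 27 surface ectoderm and epithelium genes, 2 fell over all genes, 25 did not pass, and 15 fell adjusted over the list alone, with 26 negative values and a median log2 change of -0.56. Cldn3, a tight junction claudin, fell from 7.36 ± 1.24 to 1.41 ± 0.682 FPKM, and Perp, a desmosomal membrane protein, from 10.8 ± 0.925 to 5.24 ± 0.464 FPKM. The camera adjusted p was 8.29e-13, and adjusted p = 0.338 with an estimated correlation. In neuronal differentiation genes, 2 of 22 fell, Tubb3 and Gap43, a growth cone protein that fell by 1.59 on the log2 scale, and 5 fell adjusted over the list alone. By camera the adjusted p was 0.0158, and adjusted p = 0.419 with an estimated correlation.

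Of 31 cardiac muscle genes, 3 fell, the sarcomere genes Myl3, Myh7 and Myl2, with log2 changes of -1.103, -0.86 and -0.92, and 4 fell adjusted over the list alone. The camera adjusted p was 0.0252, and adjusted p = 0.740 with an estimated correlation; without KLF12 library 3 it was 0.764. Primitive erythroid genes had 25 negative values of 25, 0 called over all genes and 3 lower adjusted over the list alone. The list means of the groups overlapped, with KLF12 library 3 at -0.340 and WT library 2 at -0.344 relative to the WT mean (exact permutation p = 0.2). The embryonic globin Hbb-y was at 2076 ± 843 FPKM in WT and 583 ± 377 in the KLF12 group, and Hba-a2 at 440 ± 181 and 156 ± 83.9. Camera gave an adjusted p of 2.71e-10, and adjusted p = 0.453 with an estimated correlation.

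Hypoxia and glycolysis genes had 3 of 31 higher and 1 lower, and 8 higher and 3 lower adjusted over the list alone. Adm, Pdk1, a pyruvate dehydrogenase kinase, and Ddit4, an inhibitor of mTORC1 signalling, rose by 2.13, 0.84 and 1.48, while Ndrg1 fell by 1.70 on the log2 scale. For this list camera gave an adjusted p of 7.97e-07, and adjusted p = 0.419 with an estimated correlation. Visceral endoderm and yolk sac genes had 30 positive values of 31 and 0 called, with 2 higher adjusted over the list alone. Mttp was at 2.78 ± 1.40 and 7.22 ± 1.02 FPKM, and Apoe, a lipoprotein component, at 113 ± 41.4 and 235 ± 57.1. The list mean of WT library 1, 0.83 above the WT mean, lay within the range of the KLF12 libraries, 0.70 to 1.13. Camera gave an adjusted p of 2.24e-12, and adjusted p = 0.453 with an estimated correlation.

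In gut endoderm genes, 1 of 14 rose, Trh, a releasing hormone precursor, and 4 rose and 1 fell adjusted over the list alone. In camera the adjusted p was 0.000171, and adjusted p = 0.338 with an estimated correlation. Sonic hedgehog and ventral neural tube genes had 0 of 21 called and 4 higher adjusted over the list alone. Foxf1 was at 18.8 ± 1.67 and 30.6 ± 1.08 FPKM and Nkx6-2 at 1.82 ± 1.1004 and 7.02 ± 2.75. The camera adjusted p was 0.000663, and adjusted p = 0.753 with an estimated correlation. Neural progenitor genes had 0 of 38 called over all genes and adjusted over the list alone; Fgf17 was at 18.4 ± 2.39 FPKM in WT and 9.59 ± 3.47 FPKM in the KLF12 group. Their camera adjusted p was 0.000533, and adjusted p = 0.763 with an estimated correlation. Both lists lost the call without KLF12 library 3, with an adjusted p of 0.256 each.

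Endothelial genes, among them Kdr and Sox7, had 0 of 24 called over all genes and adjusted over the list alone, with a camera adjusted p of 0.0252, and adjusted p = 0.338 with an estimated correlation. In the immediate early and heat shock list 1 of 19 fell, Hspb1, a small heat shock protein, from 50.03 ± 0.976 to 21.8 ± 2.71 FPKM, while 13 values were positive; 2 rose and 1 fell adjusted over the list alone. Its camera adjusted p was 0.0320 in the higher direction, and adjusted p = 0.338 with an estimated correlation. None of the 11 list calls held with an estimated correlation or with fry's directional test. For gut endoderm, endothelium and immediate early genes the estimated correlations were -0.009, -0.015 and -0.007, below the preset 0.01. A higher correlation therefore does not account for the loss of those calls. The simulated data were not put through these alternatives, so their ability to call a shifted list was not measured.

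Other lists had no camera call. Vim, an intermediate filament gene of the matrix list, fell from 304 ± 9.92 to 146 ± 27.0 FPKM. The camera adjusted p was 0.265 for apical constriction, 0.532 for Wnt, neural crest and trophoblast genes, 0.147 for BMP, 0.0648 for Notch and somite, 0.780 for matrix, 0.698 for p53 and 0.8001 for cell cycle and unfolded protein response genes. It was 0.729 for folate, Hox and interferon genes, 0.856 for retinoic acid and for KLF and SP family genes, 0.0517 for primary cilium, 0.105 for decidua and 0.850 for ribosomal protein genes. Macrophage genes with 1 and sex-linked genes with 4 tested members were too few to test, and the mitochondrially encoded and histone lists had 0.

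**Figure D2:**
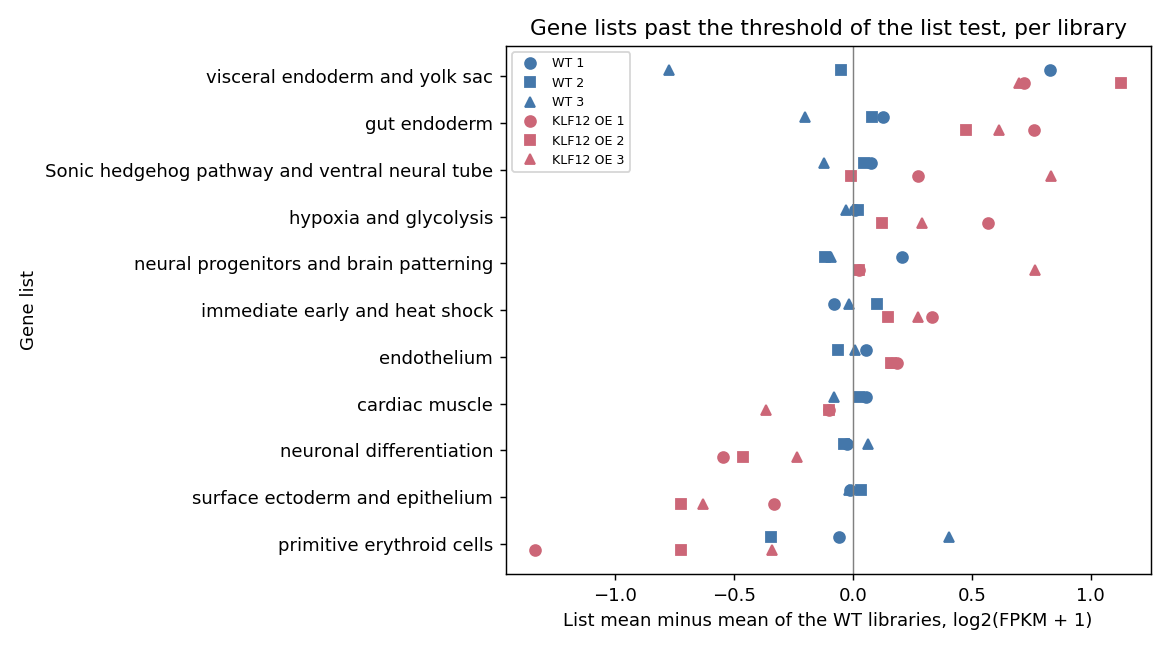
Mean of each list past the camera threshold, minus the mean of the WT libraries, on the log2(FPKM + 1) scale on the horizontal axis, for each of the 6 libraries. The surface ectoderm means of the KLF12 libraries were -0.33, -0.72 and -0.63, all below WT, while those of the yolk sac list overlapped with WT.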

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

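Klf12 kept its direction and its call in each alternative run, with a log2 difference of 2.59 to 3.28. The 89 called genes kept their direction in each alternative that tested them. As the groups of all 89 did not overlap, only another scaling or the removed length trend could have reversed a direction. The number called did not hold. It was 17 to 326 with each replicate left out, 2 to 90 higher and 15 to 236 lower. Fewer genes were called without a filter (29, 4 higher and 25 lower) and as TPM (51, 5 higher and 46 lower). There were 6 higher genes at a mean of at least 5 FPKM and also without erythroid and ribosomal genes, an alternative that was also to leave out the mitochondrial list, which had 0 tested members. Array weights gave 1585 (560 higher, 1025 lower), an adjusted p under 0.1 gave 173 (27 and 146), and groups that did not overlap gave 2049 (959 and 1090), 16.9% of genes against 10% by chance. Alternatives added after seeing the data gave 141 (25 and 116) with the length trend removed and 919 (332 and 587) in the 4 libraries with Y-linked values. The cause was not tested in these cases.

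No pairing by replicate number was visible, since deviations of same-numbered libraries correlated by 0.03, -0.11 and 0.04. These values cannot settle whether such samples shared a litter or a batch. With the replicate block 64 genes were called, Notch and somite genes gained a call (adjusted p 0.0368) and immediate early genes lost theirs (0.0549).

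For the lists, 0 calls held with an estimated correlation and 0 with fry's directional test. Adjusted p with an estimated correlation and by fry were 0.753 and 0.605 for Sonic hedgehog, 0.763 and 0.649 for neural progenitors, 0.419 and 0.224 for neuronal differentiation, 0.338 and 0.0778 for surface ectoderm, 0.419 and 0.232 for hypoxia, 0.338 and 0.232 for immediate early, 0.453 and 0.292 for erythroid, 0.740 and 0.292 for cardiac, 0.338 and 0.113 for endothelium, 0.453 and 0.331 for yolk sac and 0.338 and 0.0726 for gut endoderm genes. Fry's mixed test lost Sonic hedgehog (0.145), neural progenitors (0.0998), erythroid (0.163), endothelium (0.370) and yolk sac (0.170). It gained Wnt (0.00273), p53 (0.0106), folate (0.000799), KLF and SP (0.000799) and unfolded protein response genes (0.0175). The KLF and SP list holds Klf12 itself, its only called member, and no value without Klf12 is given.

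Without a filter, Notch gained a call (0.0341) and neuronal (0.0564), immediate early (0.0851) and cardiac genes (0.0623) lost theirs. A mean of at least 5 FPKM lost immediate early (0.488) and endothelium (0.107). Notch also passed with median-of-ratios scaling (0.0471) and quantile normalization (0.0387). Immediate early genes lost the call as TPM (0.0775) and without erythroid and ribosomal genes (0.0601). Primary cilium passed without the variance trend (0.0436). Array weights gained BMP (0.0138), Notch (0.0125), Hox (0.0390) and ribosomal genes (1.27e-07) and lost neural progenitors (0.103) and cardiac genes (0.567). Ribosomal genes passed with the length trend removed (0.00182). In the 4 libraries with Y-linked values, neural tube closure (9.02e-05) and ribosomal genes (4.55e-31) turned direction with a call, planar cell polarity (0.000717) and matrix genes (0.00114) gained one, and neuronal (0.2497), immediate early (0.200), endothelium (0.192) and gut endoderm genes (0.118) lost theirs.

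With each replicate left out, adjusted p ranged from 0.00183 to 0.974 for neural tube closure, 0.0297 to 0.941 for planar cell polarity, 0.0373 to 0.824 for apical constriction, 1.47e-06 to 0.256 for Sonic hedgehog, 0.0115 to 0.780 for BMP, 0.00195 to 0.462 for Notch, 3.55e-06 to 0.256 for neural progenitors, 0.000415 to 0.904 for matrix, 0.0305 to 0.163 for primary cilium, 0.00851 to 0.134 for immediate early, 0.000945 to 0.764 for cardiac, 0.0187 to 0.0814 for endothelium and 1.97e-24 to 0.906 for ribosomal genes, which were called lower at 0.0472 without KLF12 library 1. Relative to the WT mean, the ribosomal list mean was 0.17, 0.19 and -0.36 in KLF12 libraries 1, 2 and 3, so its direction depended on library 3. Of the 29 called genes besides Klf12 that the rule for named genes picked, 7 kept direction and call in all settings that tested them. Of the 29, 0 reversed with a call, which their separate groups fixed in advance except under other scalings and the removed length trend.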

Other observations

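Tests of the gene count against other splits, of fetal sex, of the fragment number and of library 3's length trend (both) were chosen after the results were seen. So were those of Hox genes, of yolk sac against blood and of neighbouring genes. The test of the list count against other splits was not. The length trend in the called genes was tested with a fit that was added after the data were seen.

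Of 8 annexin genes tested, 5 were called lower by limma, Anxa2, Anxa5, Anxa6, Anxa7 and Anxa11, and 8 had negative values, with a median log2 change of -1.52. Anxa1, Anxa3 and Anxa4 were not called (adjusted p 0.430, 0.356 and 0.310). Of 7 S100 genes, 3 were called lower, S100a6, S100a10 and S100a11, and 4 had negative values, while S100a1, S100a13 and S100g were at 0.12, 0.12 and 0.26. The numbers of negative values were the same under each of the other 4 scalings, where 4 or 5 annexins and 2 or 3 S100 genes were called lower. No fixed list held these families, which were picked after the values were seen, so no chance level is given. Msn, a membrane-actin linker, was at 67.6 ± 4.90 FPKM in WT and 28.2 ± 0.855 in the KLF12 group, and Iqgap1, a scaffold protein, at 20.1 ± 0.726 and 4.04 ± 1.11 (SD, n = 3), both called lower by limma and also chosen after their values were seen.

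The called genes were mostly lower, 77 of 89. With 10 splits of the 6 libraries a share under 0.05 cannot be reached: 1 split, the real one, gave as many, and the highest other gave 2. A length trend is argued against as the whole source, since 84 of the 84 called genes with a transcript length stayed called once it was removed. For fetal sex, over 326 genes called without KLF12 library 3, which has Y-linked values, the median ratio of its change to that of libraries 1 and 2 was 0.481, with quartiles of -0.09 and 0.94, against -0.06 to 0.08 with a WT library in its place. The median lay above that range, which is also of medians, while the quartiles are of single genes. The WT libraries helped to pick these genes, so that range lies near 0 by construction. Lying above it therefore does not decide on fetal sex. KLF12 libraries 1 and 2 also helped to pick them, which can pull the ratio below 1 whatever the cause. Of the 236 genes called lower without library 3, 181 were also lower in it, and of the 90 called higher, 52 were also higher. These values rest on 1 KLF12 library, so sex stays open, as does overexpression itself, which was not tested apart from it.

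KLF12 library 3 stood apart from the others. Its estimated number of fragments was 0.940 of the median of the others, which argues against low depth. A length trend may contribute: across 11674 genes, which are not independent replicates, its deviation from the WT mean correlated with transcript length by a Spearman rho of 0.421, against -0.22 and 0.05 for KLF12 libraries 2 and 1, while from the other KLF12 libraries, a measure in which each contains the others, it was 0.430 in library 3 and -0.465 in library 2. It is argued against as the whole source, since with the trend removed the SD of library 3 around its group mean was 0.299, 1.22 times the next highest, 0.245. Before removal these SDs were 0.333 in library 3 and 0.275 in KLF12 library 2. Both fell, so by this measure the lead of library 3 hardly changed. No biological explanation was tested.

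The erythroid, neuronal and cardiac lists passed camera in the lower direction with the preset correlation, but not with an estimated one (adjusted p = 0.453, 0.419 and 0.740), and list calls were common in other splits: 6 of the 10 splits, the real one included, gave at least its 11 called lists, and the highest other gave 14. An earlier stage of the KLF12 fetuses is a candidate explanation: the median log2 change of the 5 tested Hox genes of groups 10 to 13 was -0.48, against 0.03 for groups 1 to 4. In the mean of these 5 genes, KLF12 library 3, at -0.15, was only just below the lowest WT library, at -0.13 (exact permutation p = 0.1, the smallest possible). Gene by gene, 0 of the 31 tested Hox genes were called. None had all KLF12 values below all WT values, while 4 had them all above. If different amounts of yolk sac and blood were taken with the fetus, and varied together, the yolk sac and erythroid list means would move alike. They correlated in the opposite direction, with Pearson's r = -0.643 (exact permutation p = 0.175, 1 relation tested) and Spearman's rho = -0.486 (p = 0.356 by the same test). Without the 2 libraries farthest from the median r was 0.03, so the relation rests on those and cannot decide this explanation. It also does not bear on amounts that varied separately.

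Rps6kb2, called higher, and Rad9a, called lower, lie 5 genes apart on chromosome 19 in the GRCm38.p6 annotation. Over all called genes, 4 pairs lay within 10 annotated genes of each other, and a share of 0.126 of 10000 random draws of tested genes had as many, so chance could account for them.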
